A study of Arabidopsis thaliana with 13 samples.

How the data were processed

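RNA was measured in 13 libraries of Arabidopsis thaliana (Col-0) root cells, sorted by fluorescence from roots that were protoplasted 5 days after germination. Per the labels' protocols, cDNA was made and amplified with a low-input SMARTer kit, fragmented by ultrasound and made into libraries with a low-input kit. No molecular identifiers are named in the labels, so reads of 1 gene are not independent molecules. The labels call the libraries of a group biological replicates.

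The values are FPKM (fragments per kilobase of transcript and per M mapped fragments, M being the prefix mega), as deposited by the authors in 1 table of 33560 genes. Cufflinks is named without a version, per the submitters' processing notes. The aligner, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. Gene names, biotypes, exon lengths and neighbours came from the RefSeq table of the TAIR10.1 assembly, which held 32826 of the 33560 identifiers and a symbol for 10658. Whether fragments were counted by strand is not given in the sources used here, so fragments of overlapping genes cannot be told apart. Apart from strand, fragments of close paralogs may also be assigned to the wrong gene.

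Libraries were assigned to 4 groups from their titles: QC-marker cells (WOX5::GFP) of the wild type (n = 3) and of wox5-1 (n = 4), and CEI-marker cells (CYCD6::GUS-GFP) of the wild type (n = 3) and of wox5-1 (n = 3). The columns of the CEI-marker libraries name their group and a number. Those numbers (1, 3 and 4 in the wild type, and 1, 2 and 4 in wox5-1) do not match the replicate numbers of the titles, so they are used here only as names.

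Depth was estimated from the table itself. In genes with 1 transcript and at least 1000 bases of exon, FPKM values are multiples of the value of 1 fragment, and the step gives the number of mapped fragments, printed in M. Between 34.5% and 47.7% of the values used lay within 0.1 fragments of a whole number, where chance gives 20% for a step fixed in advance. The step and a length offset were chosen to maximise that share, so the excess over 20% is overstated. On 4 simulated libraries, in which most genes had whole counts, the largest relative error was 2.6%. The error may be larger in the real libraries. The estimate describes depth and entered no test.

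The main test was limma (3.58.1, R 4.3.3) on log2(FPKM + 1) with a mean-variance trend, 2-sided. The 13 libraries entered 1 fit with a mean per group and 9 residual degrees of freedom, to which the shared estimate of the spread added 5.28. Genes with an FPKM of at least 1 in at least 3 libraries were tested, 21574 in number. Benjamini-Hochberg adjustment ran over the genes tested, and a gene was called at an adjusted p under 0.05. Changes are on the log2(FPKM + 1) scale, which understates those of low genes. On simulated data for the wox5-1 against wild-type comparison of QC-marker cells, 0 of 50 genes changed by 1 on the log2 scale were recovered, 11 of 50 changed by 2, 32 of 50 changed by 4 and 43 of 50 changed by 6. Of the 88 genes called there, 2 were false. At the same 4 sizes, 0, 12, 26 and 37 of 50 were recovered in CEI-marker cells (2 of 77 calls false), 0, 4, 30 and 39 between populations in the wild type (4 of 77), 0, 13, 30 and 37 between populations in wox5-1 (2 of 82), and 0, 1, 20 and 31 for the difference of effects (2 of 54). Camera called the 1 list that was changed and 1 other. All these simulations gave a gene the same SD in every library. The real groups differed in spread (median SD 0.924 in wild-type and 0.263 in wox5-1 QC-marker cells). Recovery and false calls may therefore differ in the real data.

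Before the data were examined, 21 gene lists with 258 loci were fixed from textbook knowledge: the study network, markers of root cell types and of green tissue, and lists for cell division, auxin, cytokinin, WOX and GRF families, starch, heat shock and wounding. Lists with at least 5 tested members were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Each call was repeated with an estimated correlation and with fry. The count of members called is given over all genes and adjusted over the list alone.

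The genes named in the report follow a rule fixed at the same time. In every comparison it takes WOX5, PAN, AN3, SHR, SCR and CYCD6;1. In the first 3 comparisons it takes, among called genes with a symbol whose groups do not overlap, the 10 with the largest increase and the 10 with the largest decrease. It takes 5 of each in wox5-1 and in the difference of effects, without the overlap condition in the latter. In each list that is called or holds called members, it takes up to 4 members with the smallest adjusted p. The report leaves out some of these genes that were not called. Results for 1 further gene are not reported here.

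The alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, no trend, array quality weights, only the groups compared, a replicate block, a 2-fold minimum and leaving out each library. After seeing the data 5 more were added: lists without WOX5, a block on the column number, scaling to the nuclear total without genes near ribosomal DNA, a mean FPKM of at least 10, and leaving out 3 doubted libraries together. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for the figures.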

Results

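The series profiled the transcriptomes of sorted Arabidopsis root cells with and without WOX5, a homeobox transcription factor of the quiescent centre (QC), the slowly dividing core of the root stem cell niche. Its title concerns feedback between PERIANTHIA (PAN, a bZIP transcription factor), WOX5 and GRF-INTERACTING FACTOR 1 (AN3, a transcriptional coactivator). QC-marker cells carried WOX5::GFP, and CEI-marker cells carried CYCD6::GUS-GFP, a reporter of the D-type cyclin CYCD6;1. Each population was sorted from the wild type and from the wox5-1 mutant, with 3 libraries per group and 4 for wox5-1 QC-marker cells.

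The wild-type QC-marker libraries were shallower than the others. They held an estimated 6.9, 5.8 and 8.1 M fragments (M, mega), against 24.8 to 38.1 M in wox5-1 QC-marker cells, 19.5 to 32.8 M in wild-type CEI-marker cells and 18.0 to 30.9 M in wox5-1 CEI-marker cells. Wild-type QC-marker library 2 listed 19783 genes at 0, against 5385 to 12971 in the other 12 libraries. The median within-group SD of log2(FPKM + 1) was 0.924 in wild-type and 0.263 in wox5-1 QC-marker cells, and 0.685 and 0.553 in wild-type and wox5-1 CEI-marker cells. ACT2, ACT7, UBQ10, GAPC2, PP2AA3 and TUB4, which every cell uses, were above 0 in every library, but not all were level. ACT2 was at 720, 274 and 1221 FPKM in wild-type and at 1584 to 2461 FPKM in wox5-1 QC-marker cells. UBQ10 was at 327, 576 and 326 FPKM in wild-type and at 607.1 to 739.5 FPKM in wox5-1 QC-marker cells. ACT7, GAPC2, PP2AA3 and TUB4 overlapped between these groups.

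**Figure D1:**
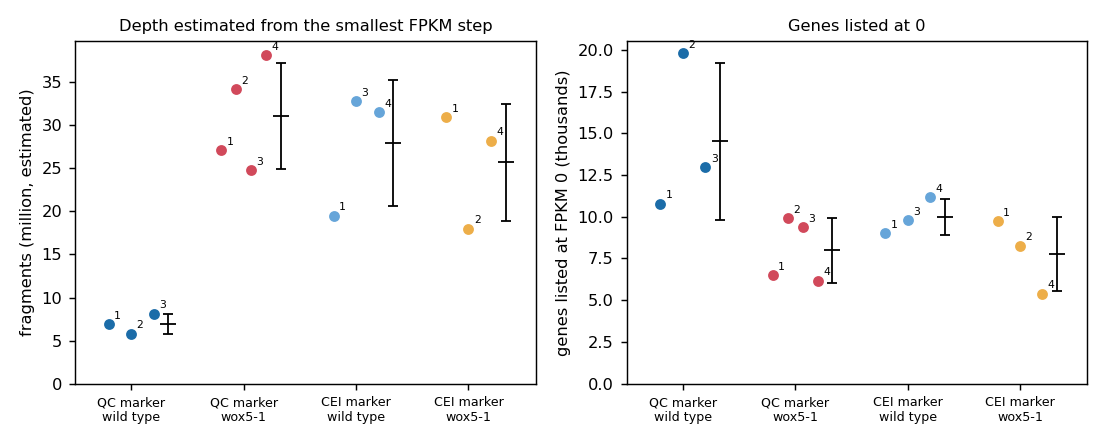
Estimated depth in M fragments (left) and genes listed at an FPKM of 0 (right), per library. Points are libraries with their numbers, and bars are the mean and SD of each group.

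WOX5 (AT3G11260), the mutated gene, was listed at 255, 262 and 163 FPKM in the 3 wild-type QC-marker libraries and at 0, 0.114, 0.0785 and 0.0528 FPKM in the 4 wox5-1 libraries. Its log2 change was -7.71 (SE 0.83, adjusted p = 0.000784). In CEI-marker cells WOX5 was at 8.82, 27.3 and 0 FPKM in wild-type libraries 1, 3 and 4, and at 0, 0 and 0.207 FPKM in wox5-1 libraries 1, 2 and 4. That change of -2.62 (SE 0.88) did not pass the test (adjusted p = 0.527). Without wild-type library 4 it was -3.97 and passed (adjusted p = 0.048). The 0 in the library labelled wild type 4 leaves WOX5 unable to check its label.

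Among the other genes of the study network, none passed the test over all genes in either genotype comparison. AN3 (AT5G28640) averaged 96.1 ± 17.2 FPKM (SD, n = 3) in wild-type and 23.0 ± 6.04 FPKM (SD, n = 4) in wox5-1 QC-marker cells, a log2 change of -2.03 (SE 0.75, adjusted p = 0.152). CYCD6;1 (AT4G03270) was at 0.658, 0 and 2.07 FPKM in wild-type and averaged 5.09 ± 0.568 FPKM (SD, n = 4) in wox5-1 QC-marker cells, a log2 change of 1.82 (SE 0.71, adjusted p = 0.171). PAN (AT1G68640) was at 24.9, 0 and 31.2 FPKM in wild-type QC-marker cells, the 0 being in library 2, and averaged 16.8 ± 6.0 FPKM (SD, n = 4) in wox5-1. Its log2 change was 0.86 (SE 1.05, adjusted p = 0.675), and turned to -0.76 (SE 0.75, adjusted p = 0.672) without library 2. SHR (AT4G37650) and SCR (AT3G54220), transcription factors that pattern the ground tissue, had log2 changes of 0.14 (SE 0.59) and 0.09 (SE 0.67), which turned to -0.49 (SE 0.51) and -0.38 (SE 0.72) without that library. Adjusted over the list alone, WOX5 included, 1 member of the network rose and 2 fell in QC-marker cells. The set test with WOX5 did not call the network there (adjusted p = 0.138, and adjusted p = 0.84 with an estimated correlation). Without WOX5 the adjusted p was 0.74. Without library 2 the network with WOX5 was called lower (median -0.63, adjusted p = 0.0399). The network without both WOX5 and library 2 was not tested.

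**Figure D2:**
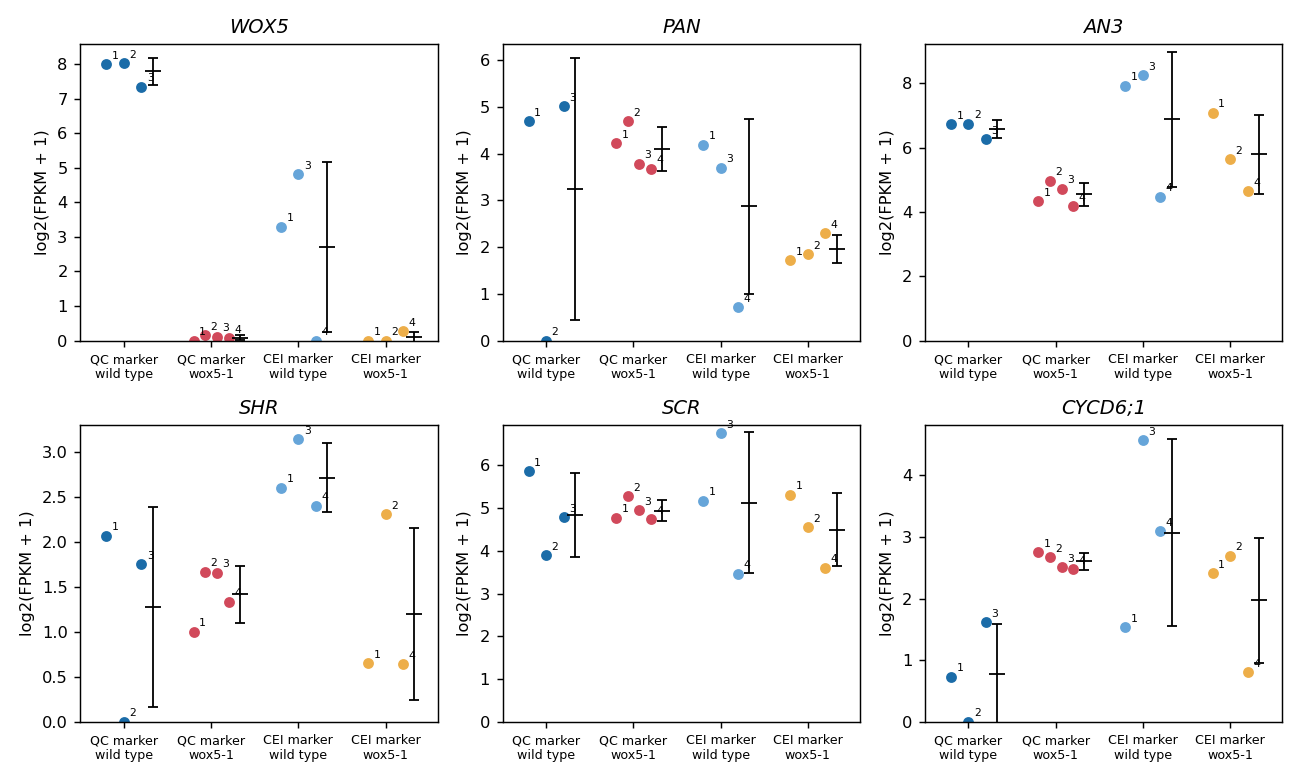
Transcript level of the 6 network genes as log2(FPKM + 1) in the 13 libraries. Points are libraries with their numbers, and bars are the mean and SD of each group.

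The first comparison asked which transcripts changed in QC-marker cells that lack WOX5. The largest increases among called genes with a symbol were in AOC1 (log2 change 5.37, SE 1.01), an enzyme of jasmonate synthesis, MSRB8 (5.18, SE 0.86), a methionine sulfoxide reductase, and AAP1 (5.12, SE 0.61), an amino acid permease. GSTU6, a glutathione transferase, averaged 60.5 ± 81.0 FPKM (SD, n = 3) in the wild type and 757 ± 65.8 FPKM (SD, n = 4) in wox5-1 (log2 change 4.94, SE 0.85). ERF53 (4.90), HA7 (4.79), the signalling peptide gene CLE1 (4.74), CYP81D11 (4.71), IAMT1 (4.70), which methylates auxin, and RAP2.9 (4.58) also rose. After WOX5, the largest decreases among called genes with a symbol and no overlap were in the kinase gene WAG1 (-3.73, SE 0.93), EXPA14 (-3.36), an expansin, and WRKY38 (-2.87). RTFL15 (-2.80), GATA3 (-2.69), SHP1 (-2.64), BRS1 (-2.61), BR6OX2 (-2.49), a brassinosteroid synthesis enzyme, and SOB3 (-2.41) also fell.

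Limma called 741 of 21574 genes in this comparison, 659 higher and 82 lower in wox5-1. All tested genes had a median log2 change of 0.319, which was 0.265 with median-of-ratios scaling and -0.07 with quantile normalization. The calls were then 356 higher and 59 lower, and 343 higher and 111 lower. Without wild-type library 1 the count was 1514. Without wox5-1 libraries 1, 2, 3 and 4 it was 200, 247, 203 and 199. Of the 26 named genes called, 11 passed the test without each library in turn: WOX5, JAZ8, AAP1, ERF53, GSTU6, AOC1, SHP1, HA7, RAP2.9, MSRB8 and IAMT1. The values of 5094 genes, or 23.6%, did not overlap between the groups, where chance gives 5.7% if libraries are interchangeable. The groups differed in spread (median SD 0.924 in the wild type and 0.263 in wox5-1), which alone can raise that share. The excess over 5.7% is therefore no measure of a genotype effect.

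**Figure D3:**
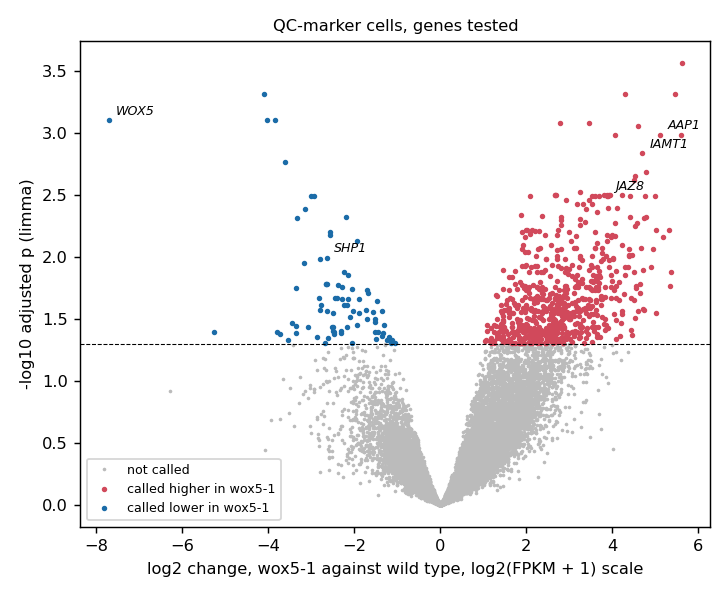
Change of each tested gene in QC-marker cells of wox5-1 against the wild type, on the log2(FPKM + 1) scale, against the -log10 adjusted p of limma. The dashed line is an adjusted p of 0.05.

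The wounding and jasmonate list rose as a set in wox5-1 QC-marker cells (median log2 change 1.48, adjusted p = 0.000531, and adjusted p = 0.531 with an estimated correlation). Of its 14 tested members 4 were called higher, and 8 adjusted over the list alone. The 4 were the jasmonate repressor genes JAZ8 (log2 change 3.89, SE 0.54), JAZ7 (3.49, SE 0.74) and JAZ10 (3.16, SE 0.63), and WRKY40 (2.46, SE 0.55), a stress-response transcription factor. The QC and niche list fell as a set (median -0.49, adjusted p = 0.00219, and adjusted p = 0.0894 with an estimated correlation). Of its 16 tested members, 1 was called lower, WOX5 itself, and 2 adjusted over the list alone. Without WOX5 the median was -0.39 (adjusted p = 0.0421, and adjusted p = 0.445 with an estimated correlation). MYB56, which restrains QC division, averaged 58.9 ± 28.2 FPKM (SD, n = 3) in the wild type and 4.18 ± 1.09 FPKM (SD, n = 4) in wox5-1, just outside the threshold (log2 change -3.43, SE 0.89, adjusted p = 0.0511). TEL1 (-1.82) and AGL42 (-1.13) did not pass.

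The list of G2 and M phase genes was called lower relative to other genes (adjusted p = 0.0421, and adjusted p = 0.84 with an estimated correlation), although its median was 0.16, its mean -0.13, and 0 of 22 members were called. The call was lost without wild-type library 1 (adjusted p = 0.232) or 3 (0.201) or wox5-1 library 4 (0.0746). Without wild-type library 2 the median was -0.66, the mean -0.58 and the adjusted p = 0.000272. AUR1 (-1.23), CDC20.2 (-1.02), CDKB1;2 (-1.06) and CYCB2;3 (-1.50) had the smallest adjusted p. In the WOX family WOX7 rose (log2 change 4.1, SE 0.95, adjusted p = 0.0324), and WOX13 (1.82) and WOX6 (-0.54) did not pass. WOX7 was at 0.982, 0 and 0 FPKM in the shallow wild-type libraries, and passed in 7 of the 13 fits that left out 1 library. CLE40, a peptide gene of the columella list, rose (2.43, SE 0.53, adjusted p = 0.0256), while PIN7 (2.66), FEZ (1.80) and BRN2 (-2.86) did not pass. CLE40 was at 0, 0 and 2.325 FPKM in the wild type, and passed in 8 of those 13 fits. Epidermis and root hair had a median of 1.89, and was called higher by fry (adjusted p = 0.00898) but not by camera (adjusted p = 0.371). No member was called over all genes, and 3 of 10 were higher adjusted over the list alone. Camera and fry did not call the other lists. Their medians were 0.02 for young ground tissue, 0.54 for differentiating endodermis, 0.51 for stele and pericycle, 0.31 for S phase and replication, 0.68 for D-type cyclins, 0.80 for CDK inhibitors, 0.25 for green tissue, 0.35 for auxin response, 0.13 for auxin synthesis and transport, 0.01 for type-A response regulators, -0.36 for the GRF and GIF family, 0.12 for starch synthesis and -0.24 for heat shock. The cortex list held 2 genes (median 1.58) and was not tested as a set. Several of these medians rest on wild-type library 2. Without it they were -0.43 for young ground tissue, -0.73 for differentiating endodermis, 0.33 for stele and pericycle, 0.91 for epidermis and root hair, -0.26 for S phase and replication, 0.03 for D-type cyclins, 0.18 for CDK inhibitors, 0.19 for auxin response, 0.32 for auxin synthesis and transport, -0.06 for type-A response regulators and 0.43 for starch synthesis. None of these lists was then called, while the GRF and GIF family was called lower (-0.72, adjusted p = 0.0343). The median of all tested genes was then 0.122.

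Mean library composition differed between the genotypes in QC-marker cells, a difference that was not tested. Chloroplast-encoded transcripts made up 1.35% ± 0.879 of summed FPKM in the wild type (SD, n = 3) and 0.335% ± 0.207 in wox5-1 (SD, n = 4). Mitochondrial transcripts made up 1.43% ± 0.642 and 0.472% ± 0.0762, and the 10 genes within 5 kb of annotated ribosomal DNA made up 0.920% ± 0.656 and 0.232% ± 0.162. Wild-type library 2 had the lowest share of each among its group, at 0.336%, 0.696% and 0.184%. The wox5-1 libraries ran from 0.142% to 0.566%, from 0.392% to 0.552% and from 0.073% to 0.383%. The chloroplast and ribosomal DNA shares therefore overlapped between the genotypes. Genotype and depth cannot be told apart in these groups.

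The second comparison asked the same of CEI-marker cells, and 6 genes were called, 4 higher and 2 lower in wox5-1. PMI1 was at 10.9, 5.77 and 3.06 FPKM in wox5-1 and at 0.02, 0.0977 and 0 FPKM in the wild type (log2 change 2.73, SE 0.41, adjusted p = 0.0357). The others have no symbol and are named because the count is small. AT2G41233 was at 28.3, 21.6 and 14.4 FPKM in wox5-1 and listed at 0 in the other 10 libraries. AT2G24880 (2.51) and AT4G22214 (3.95) also rose. The mitochondrial ATMG00360 was at 39.6, 12 and 12.2 FPKM in the wild type and listed at 0 in the other 10 libraries, and AT2G40450 (-2.50) also fell. Where a gene was at 0 in QC-marker cells, those libraries lowered its shared estimate of the spread. With only the CEI-marker libraries in the fit, 0 genes were called. The count at an unadjusted p under 0.05 was 1734. The count of 6 was 3 without wild-type QC-marker library 3, 3, 2 and 2 without wox5-1 QC-marker libraries 1, 3 and 4, 3 and 14 without wild-type CEI-marker libraries 1 and 3, and 25, 1 and 1 without wox5-1 CEI-marker libraries 1, 2 and 4. PMI1 entered the test in 10 of the 13 fits and passed in 1 of them, the one without wild-type QC-marker library 1.

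In CEI-marker cells the QC and niche list was lower in wox5-1 as a set (median -0.77, adjusted p = 0.000653, and adjusted p = 0.0442 with an estimated correlation). The list includes WOX5 (-2.62), and without it the median was -0.67 (adjusted p = 0.0019, and adjusted p = 0.112 with an estimated correlation). None of its 16 tested members was called over all genes, and 2 were lower adjusted over the list alone. PLT3 averaged 56.1 ± 11.9 FPKM (SD, n = 3) in the wild type and 15.0 ± 9.29 FPKM (SD, n = 3) in wox5-1 (log2 change -1.96, adjusted p = 0.167), and PLT1, another PLETHORA regulator of the stem cell niche, had a log2 change of -1.29 (adjusted p = 0.458). That of RGF3 was -1.77 (adjusted p = 0.563). The study network was also lower as a set (median -1.10, adjusted p = 0.00259, and adjusted p = 0.402 with an estimated correlation), with SHR at -1.52, CYCD6;1 at -1.10, AN3 at -1.09, PAN at -0.91 and SCR at -0.64, none called. Without WOX5 the network had an adjusted p = 0.0212, and 0.574 with an estimated correlation. The network call was lost without wild-type library 3 (adjusted p = 0.118).

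Lists of S phase and replication (median -0.94, adjusted p = 0.000828), G2 and M phase (-0.49, adjusted p = 0.021) and auxin synthesis and transport (-0.60, adjusted p = 0.0425) were lower in wox5-1 CEI-marker cells. Each had an adjusted p = 0.53 with an estimated correlation. Epidermis and root hair (1.33, adjusted p = 0.0212) and type-A response regulators of cytokinin (0.64, adjusted p = 0.0318) were higher, each with an adjusted p = 0.187 with an estimated correlation. No member of these 5 lists was called over all genes, and 1 response regulator was higher adjusted over the list alone. Among the members with the smallest adjusted p were PCNA2 (-1.0), MCM3 (-1.14), CYCA3;1 (-1.07) and TSO2 (-0.99) in S phase, CYCB2;1 (-1.69), CYCB2;4 (-1.05), AUR1 (-0.54) and CDC20.2 (-0.52) in G2 and M phase, YUC3 (-0.96), PIN4 (-0.86) and AUX1 (1.16) in auxin, RHD6 (2.17), RSL4 (1.78), EXPA7 (1.99) and PRP3 (2.25) in root hair, and ARR9 (1.33), ARR8 (0.84), ARR7 (1.02) and ARR5 (0.64) among the regulators. The S phase call was lost without wox5-1 library 2 (adjusted p = 0.123), and that of G2 and M phase without wild-type library 1 (0.216) or 3 (0.267) or wox5-1 library 1 (0.192). The auxin list turned upward without wild-type library 4 (0.82), and its call was lost without wox5-1 library 1 (0.104) or 4 (0.123) or wild-type QC-marker library 2 (0.0653). Without wild-type library 1 or 4 or wox5-1 library 1 the epidermis call was lost (0.0534, 0.0548 and 0.0781), as was that of the response regulators (0.0854, 0.0573 and 0.109), the latter also without wox5-1 library 4 (0.0571).

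The green tissue list was higher as well (median 3.55, adjusted p = 0.00198, and adjusted p = 0.53 with an estimated correlation), and its level came from 1 library, wox5-1 library 1, without which it was not called (adjusted p = 0.356). RBCS1A, the small subunit of Rubisco, was at 6010 FPKM in wox5-1 CEI-marker library 1 and at 3.68 and 19.7 FPKM in libraries 2 and 4. LHCB1.3 and LHCB1.1, chlorophyll-binding proteins, were at 2670 and 1390 FPKM in that library. Wild-type CEI-marker library 4 stood apart in root cap genes, chosen after their values were seen, with CEL5 at 1950 FPKM and BRN1 at 208 FPKM, against 8.63 to 141 and 0.232 to 52.4 FPKM in the other 5 CEI-marker libraries. Its AN3 was at 21.2 FPKM, against 243 and 306 FPKM in wild-type libraries 1 and 3. In wox5-1 libraries 1, 2 and 4 AN3 was at 135, 49.1 and 24.1 FPKM.

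**Figure D4:**
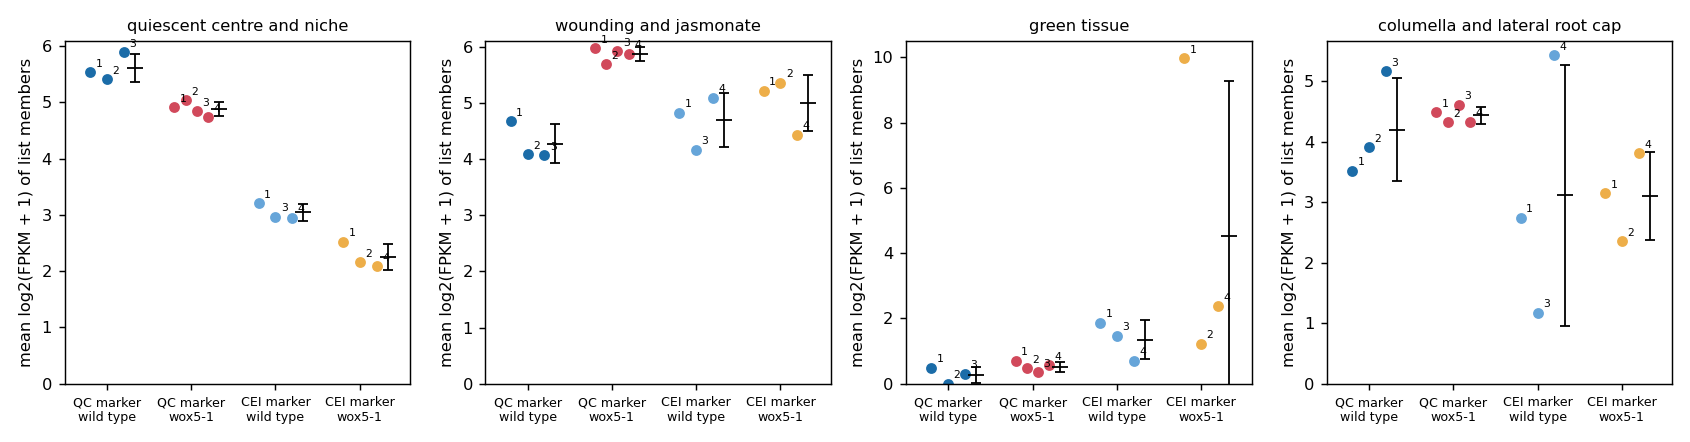
Mean log2(FPKM + 1) over the members of 4 lists in the 13 libraries. Points are libraries with their numbers, and bars are the mean and SD of each group.

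The third comparison, between the 2 populations in the wild type, called 77 genes, 54 higher and 23 lower in QC-marker cells. WIP5, a zinc finger gene of the niche list, averaged 72.4 ± 22.8 FPKM (SD, n = 3) in QC-marker cells and was at 0, 0 and 3.33 FPKM in CEI-marker cells (log2 difference 5.45, SE 0.57, adjusted p = 0.000699). WOX5 (5.09, SE 0.88), WIP4 (4.93), HB17 (4.70), TEL1 (4.21), SHP1 (3.96), IAA30 (3.83), WIP2 (3.71), GBSS1 (3.67) and AGO10 (3.63) were the next largest among called genes with a symbol. Lower in QC-marker cells were NAC044 (-3.56), AAP1 (-3.43), IAMT1 (-3.35), ELF4 (-3.05), WRKY25 (-2.81), EHB1 (-2.42), NAKR2 (-2.41) and PME5 (-2.31). CYCD6;1 (-2.29, adjusted p = 0.267), SHR (-1.44), AN3 (-0.30), SCR (-0.28) and PAN (0.37) did not pass.

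The QC and niche list was higher in QC-marker cells (median 2.97, adjusted p = 1.88e-16), and held with an estimated correlation (adjusted p = 0.000217). Of its 16 tested members 6 were called, and 13 were higher and 1 lower adjusted over the list alone. The list holds WOX5, whose promoter drives the reporter used for sorting, so its direction checks the sort. Without WOX5 the median was 2.91 (adjusted p = 8.76e-15, and adjusted p = 0.000499 with an estimated correlation). Auxin synthesis and transport (median 1.17, adjusted p = 1.19e-05) and starch synthesis (1.35, adjusted p = 0.000133) were also higher, each with an adjusted p = 0.2 with an estimated correlation. They included the auxin synthesis genes TAA1 (3.03, SE 0.42) and YUC3 (1.91, SE 0.38) and the starch synthase GBSS1, while PIN3 (2.56, adjusted p = 0.0528) and APL4 (2.87, adjusted p = 0.0541) fell just outside the threshold. RGF1 of the niche list was higher as well (3.36, SE 0.44). Auxin response (0.71, adjusted p = 0.00134, and adjusted p = 0.336 with an estimated correlation) and columella and lateral root cap (1.08, adjusted p = 0.0273, and adjusted p = 0.747 with an estimated correlation) were higher too. Auxin response was not called without CEI-marker library 3 (adjusted p = 0.13), nor columella and lateral root cap without that library (0.812), CEI-marker library 1 (0.143) or QC-marker library 2 (0.0807) or 3 (0.269). In the WOX family WOX11 was higher (3.54, SE 0.62), and WOX12 (1.75) and WOX7 (-3.35) did not pass.

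The count of 77 was 345 without wild-type QC-marker library 1 and 21 without library 3, and 35, 20 and 222 without wild-type CEI-marker libraries 1, 3 and 4. Without wox5-1 QC-marker libraries 1 to 4, which enter through the shared spread and the filter, it was 27, 33, 28 and 38, and with only the 6 libraries compared it was 1. Median-of-ratios scaling gave 25 higher and 25 lower. Named genes that passed without each library in turn were WIP5, TAA1, HB17, SHP1 and RGF1. Those fits still share the spread of the wox5-1 libraries. With only the 6 libraries compared, at most 1 of these genes can have passed. This comparison shares the wild-type QC-marker libraries with the first, so WOX5, SHP1, AAP1 and IAMT1, called in both, are not independent results.

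The fourth comparison made the same contrast in wox5-1, where 930 genes were called, 570 higher and 360 lower in QC-marker cells. ADF9, an actin-depolymerizing factor (log2 difference 9.51, SE 1.38), the peptide hormone gene RGF2 (8.73, SE 1.37), the auxin response genes IAA33 (8.12) and IAA20 (5.38) and SGR9 (5.57) were the largest increases among called genes with a symbol. RGF2 averaged 828 ± 33.4 FPKM (SD, n = 4) in QC-marker cells and 1.53 ± 2.29 FPKM (SD, n = 3) in CEI-marker cells. The microRNA gene MIR166a (-5.47, SE 0.94), SAUR29 (-3.49), RALFL7 (-3.34) and SNG1 (-3.33) were lower. RBCS1A (-6.25) was lower too, and -3.16 (adjusted p = 0.0125) without wox5-1 CEI-marker library 1. WOX5 (-0.01, SE 0.83), SCR (0.45), CYCD6;1 (0.63), SHR (0.22), PAN (2.14, SE 1.05) and AN3 (-1.24) did not pass.

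In wox5-1 too the QC and niche list was higher in QC-marker cells (median 2.43, adjusted p = 1.51e-09), and held with an estimated correlation (adjusted p = 0.00192). Of its 16 tested members 9 were called, among them WIP5 (5.14), RGF3 (5.31), RGF1 (3.43) and PLT1 (3.0). Starch synthesis (median 1.76, adjusted p = 6.77e-06, and adjusted p = 0.145 with an estimated correlation) and auxin synthesis and transport (2.24, adjusted p = 3.44e-05, and adjusted p = 0.26 with an estimated correlation) were also higher, with PIN4 (3.14), YUC3 (3.24), TAA1 (2.44), GBSS1 (4.47), APL4 (3.70), SBE2.1 (1.89) and SBE2.2 (1.84) called. Columella and lateral root cap was higher (1.36, adjusted p = 0.0484, and adjusted p = 0.625 with an estimated correlation), with FEZ (4.6), PIN3 (3.2) and CLE40 (2.75) called. That set was not called when 1 of these 8 libraries was left out: wild-type QC-marker 1 (adjusted p = 0.0577) or 2 (0.118), wox5-1 QC-marker 4 (0.0526), wild-type CEI-marker 1, 3 or 4 (0.0554, 0.0628 and 0.0575), and wox5-1 CEI-marker 1 (0.111) or 2 (0.118). GRF and GIF family (-1.35, adjusted p = 0.0123, and adjusted p = 0.565 with an estimated correlation) and green tissue (-4.28, adjusted p = 3.79e-05, and adjusted p = 0.435 with an estimated correlation) were lower. Without wox5-1 CEI-marker library 1 the green tissue median was -1.39 (adjusted p = 0.00249) and the GRF and GIF family was not called (adjusted p = 0.0719). The GRF and GIF members GRF6 (-1.94), GRF5 (-1.97), GRF3 (-2.24) and GIF3 (1.32) did not pass. In lists not called as a set, HB8 (4.56), ARF5 (3.85), IAA30 (2.73), WOX11 (3.6), WOX12 (2.88) and JAZ5 (2.82) were higher and LBD29 (-1.99) lower.

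Of the 54 genes higher in wild-type QC-marker cells, 39 were also called higher in wox5-1. Both contrasts came from 1 fit with a shared spread per gene, so the overlap is not tested here. Of the 23 lower genes 1 was shared. Of the 32 named genes called in wox5-1, 21 passed without each library in turn. The count in wox5-1 was 2520 without wild-type QC-marker library 2, 323, 227, 248 and 505 without wox5-1 QC-marker libraries 1 to 4, and 221 and 246 without wox5-1 CEI-marker libraries 2 and 4. Without wox5-1 CEI-marker library 1 there were 581 higher and 731 lower. Median-of-ratios scaling gave 261 higher and 485 lower, and quantile normalization 553 higher and 620 lower.

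The last comparison tested whether the effect of wox5-1 differed between the 2 populations, and 5 genes were called. WAG2, a kinase gene related to WAG1, averaged 65.4 ± 17.9 FPKM (SD, n = 3) in wild-type and 13.2 ± 1.16 FPKM (SD, n = 4) in wox5-1 QC-marker cells, but 33.4 ± 13 and 70.8 ± 11 FPKM (SD, n = 3 each) in CEI-marker cells (difference of log2 changes -3.30, SE 0.49, adjusted p = 0.0363). The others, without a symbol and named because the count is small, were AT3G17100 (5.07), ATMG00360 (4.25), AT2G41233 (-4.44) and AT3G44440 (-4.31). ATMG00360 and AT2G41233 were listed at 0 in every QC-marker library. Their difference is therefore the CEI-marker change with its sign turned, and no separate result. For WOX5 the difference was -5.10 (SE 1.21, adjusted p = 0.161). CYCD6;1 (2.92, SE 1.03), PAN (1.77), SHR (1.66), SCR (0.73) and AN3 (-0.94) did not pass.

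The wounding and jasmonate list (median 1.27) and the green tissue list (-2.95) were called for a difference, each with an adjusted p = 0.0329 and an adjusted p = 0.98 with an estimated correlation. JAZ8 (4.0, adjusted p = 0.108), JAZ7 (3.46), JAZ10 (2.35) and JAZ5 (2.04) led the first, none of them called. RBCS1A (-4.54), LHCB1.1 (-3.38), RBCS3B (-3.31) and LHCA1 (-2.60) led the other and were not called either. The mean of the green tissue list was 9.98 in wox5-1 CEI-marker library 1, against 1.23 and 2.37 in libraries 2 and 4, and without that library the list was not called (adjusted p = 0.702). It was not called either without wild-type QC-marker library 1 (0.0814), 2 (0.119) or 3 (0.0616) or wild-type CEI-marker library 3 (0.0526) or 4 (0.0968). The wounding call was lost without wild-type QC-marker library 1 (0.0814) or 3 (0.271), wild-type CEI-marker library 4 (0.361) or wox5-1 CEI-marker library 1 (0.0721) or 4 (0.134). At an unadjusted p under 0.05 there were 2405 genes. The count was 59, 32 and 8 without wild-type QC-marker libraries 1, 2 and 3, 2, 2, 3 and 2 without wox5-1 QC-marker libraries 1 to 4, and 2 without wild-type CEI-marker library 1. It was 0 without each of the 3 wox5-1 CEI-marker libraries in turn. Quantile normalization gave 9 higher and 8 lower, and median-of-ratios scaling gave 1 gene, lower.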

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

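The tests of handling, of a genotype effect on photosynthesis genes and of exchanged labels were chosen after the values they measure had been seen. The others were fixed before their results were computed, except that the demand for the whole 95% interval to pass a bound was added after seeing them. The intervals run over genes, taken as independent. They do not measure the spread between libraries.

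In the 4 wox5-1 QC-marker libraries, 1 library lay far from the others in 4 of the 114 named genes, where chance alone flags about 1 in 20. The gap to the nearest library was 0.915 of the range for JAZ5 (40.3 FPKM in library 4, against 51.8 to 52.9), 0.907 for RBCS1A (0.417 FPKM in library 4), 1 for RALFL7 (0.536 FPKM in library 4, the others at 0) and 1 for LBD29 (0.112 FPKM in library 3, the others at 0).

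Because they were called in the test of the difference between the populations, 5 genes are listed: AT3G17100 (5.07), ATMG00360 (4.25), AT2G41233 (-4.44), AT3G44440 (-4.31) and WAG2 (-3.30, as a difference of log2 changes). ATMG00360 and AT2G41233 were at 0 in every QC-marker library, so their values repeat the CEI-marker result. As many calls came from 14 of 100 splits drawn from 700, with up to 418 genes, so chance is not excluded for that count of 5.

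In QC-marker cells 741 genes were called, and 1 of the 35 splits of the 7 libraries, the real one, gave as many. The highest of the other splits gave 6. A share of 1 in 35 is under 0.05, but it is the smallest that 35 splits can reach. The splits also take libraries as interchangeable, while the groups differed in spread (median SD 0.924 in the wild type and 0.263 in wox5-1). Chance is therefore not excluded by this count. For the 930 genes between populations in wox5-1 the real split was also the only 1 of 35 to give as many, with 4 as the highest other. The same limits hold there. The splits of QC-marker cells do not separate genotype from depth, since the 3 wild-type QC-marker libraries were also the shallowest.

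The first pattern is the excess of higher calls in wox5-1 QC-marker cells, 659 of 741. Among called genes with a mean of at least 50 FPKM over all libraries, 80.3% were higher (exact 95% interval over genes 74.4 to 85.3). A gene can pass that filter through its level in wox5-1, and need not be detected in the shallow libraries. The 80.3% therefore cannot weigh depth. Without wild-type library 2 the share among all called genes was 82.4% (79.2 to 85.2), and under the other scalings it was at least 75.6% (71.3 to 79.4). Shares of 80% or more had been set in advance as evidence against each cause, and none passed that bound by more than its interval. Depth, that library, scaling and the loss of WOX5 cannot be told apart here, since every wild-type QC-marker library was shallow.

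The second pattern is the higher wounding and jasmonate list in wox5-1 QC-marker cells. Without wild-type library 2 it was still called (adjusted p = 0.000145), with a median log2 change of 1.82 (95% interval 0.316 to 2.46). Its 8 members with a mean of at least 50 FPKM over all libraries had a median of 1.28 (0.507 to 3.16). Members can pass that filter through their level in wox5-1, so the 1.28 cannot weigh depth. Both medians lie above the bound of 1 set against these causes, but their intervals reach below it. Handling that differed between genotypes may also raise such genes: in CEI-marker cells the list median was 0.35 (adjusted p = 0.31), and the heat shock median in QC-marker cells was -0.24 (adjusted p = 0.371), and neither value excludes it.

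The third pattern is that 2 CEI-marker libraries stood apart from their groups. In wox5-1 library 1, 34 photosystem genes outside the fixed lists exceeded the mean of the other libraries by a median of 6.47 on the log2 scale (95% interval 5.67 to 7.09), and 31 were highest there. In the other wox5-1 CEI-marker libraries they exceeded the wild type by 0.51 (0.32 to 0.964), which argues against a genotype effect as the whole cause. Green tissue RNA in that 1 library remains possible. The library stood apart through other photosynthesis genes, so the 6.47 is no independent support for that cause. Of the 10 splits of the 6 libraries, 2 gave as many genes as the real 6. The split that exchanges wild-type library 4 with wox5-1 library 1 gave 1491. If the labels are correct, that count points to a structure of the samples other than genotype. If the 2 labels were exchanged, that split would be the one by genotype. Exchanged labels cannot be told apart from correct ones by WOX5, which was at 0 FPKM in both of these libraries.

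Between populations in the wild type, 2 of 10 splits gave as many genes as the real 77, and the highest other gave 278. With 10 splits, as for the CEI-marker comparison, no share under 0.05 can be reached.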

How the results depend on the processing

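Lists without WOX5, the block on the column number, the nuclear total, a mean FPKM of at least 10 and leaving out 3 doubted libraries were chosen only after the data were seen. WOX5 in QC-marker cells passed the test under every alternative, with log2 changes from -10.48 (pseudocount 0.1) to -5.49 (pseudocount 5). Of 185 results of named genes 12 turned sign under some alternative, none of them called. The counts of calls moved, and the cause was not tested. A 2-fold minimum changed no count.

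In QC-marker cells the 741 calls became 420 without a filter, 415 with median-of-ratios scaling, 454 with quantile normalization and 1251 with array quality weights, and ran from 199 without wox5-1 library 4 to 1514 without wild-type library 1. In CEI-marker cells the 6 calls became 91 without a filter, 2 with a filter at 5 FPKM, 2 with quantile normalization, 2 without the trend, 14 with array quality weights, 0 with only the groups compared and 0 at a mean of at least 10 FPKM. They ran from 1 without wox5-1 library 2 to 25 without wox5-1 library 1. Their WOX5 change was -4.32 with a pseudocount of 0.1 and -1.37 with a pseudocount of 5, and over left-out libraries it ran from -3.97 without wild-type library 4 to -1.56 without library 3.

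Between populations in the wild type the 77 calls became 46 with a pseudocount of 0.1, 51 without a filter, 50 with median-of-ratios scaling and 1 with only the groups compared, and ran from 20 without CEI-marker library 3 to 345 without QC-marker library 1. In wox5-1 the 930 calls became 526 with a pseudocount of 0.1, 7502 with array quality weights and 5298 with only the groups compared, and ran from 221 without CEI-marker library 2 to 2520 without wild-type QC-marker library 2. For the difference of effects the 5 calls became 15 without a filter, 0 with a filter at 5 FPKM, 1 with median-of-ratios scaling, 17 with quantile normalization, 67 with array quality weights, 3 with the nuclear total and 2 at a mean of at least 10 FPKM. They ran from 0 without wox5-1 CEI-marker library 1 to 59 without wild-type QC-marker library 1.

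The replicate block on QC-marker libraries 1 to 3 gave 174 calls in QC-marker cells, but it also leaves out wox5-1 library 4, which alone gave 199. The block on the column number gave 2 in CEI-marker cells, 25 in the wild type and 0 for the difference of effects, and changed no other count by over 1.5 times. Residuals of libraries with the same number correlated at 0.031, 0.09 and -0.057 in QC-marker cells. These values show no pairing by number there, but cannot exclude it. In CEI-marker cells column numbers 1 and 4 gave 0.276 and 0.257, against -0.273 to 0.086 for unlike numbers. Whether libraries of the same number share a batch was not tested.

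Without the 3 doubted libraries (wild-type QC-marker 2, wild-type CEI-marker 4 and wox5-1 CEI-marker 1) the counts were 1851, 4574, 700, 6650 and 2979 in the order above, and WOX5 in CEI-marker cells changed by -3.92. These libraries were picked by how their values looked, so these counts are no evidence for an effect of genotype.

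Of the 24 list calls 3 remained with an estimated correlation. Fry called 11 lists, of which 10 are among the 24. Without WOX5 in the lists 24 calls were made. Auxin synthesis and transport in CEI-marker cells had an adjusted p = 0.000111 without wild-type library 3, and turned upward without library 4 (adjusted p = 0.82). Estimated depth of 5.8 to 8.1 M fragments in wild-type QC-marker cells limits what can be said of low genes there.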

Other observations

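The test below was chosen after the values had been seen. Within the CEI-marker groups, libraries differed in cell type genes. The mean log2(FPKM + 1) of the columella and lateral root cap list was 2.74, 1.17 and 5.43 in wild-type libraries 1, 3 and 4, and 3.15, 2.35 and 3.81 in wox5-1 libraries 1, 2 and 4. The young ground tissue list was at 3.58, 4.70 and 2.72, and at 3.67, 3.22 and 2.67. A varying share of root cap cells among the sorted cells may link them, and would make the lists run against each other. Over the 6 libraries Spearman's rho was -0.71 (exact permutation p = 0.136) and Pearson's r was -0.84 (exact permutation p = 0.05), and r was -0.56 without the 2 libraries farthest from the median in root cap genes. Only this relation was computed, it pools both genotypes, and 6 libraries do not settle it.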
